A study of Mus musculus with 3 samples.

How the data were processed

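The data were chromatin immunoprecipitation followed by sequencing (ChIP-seq) of cultured wild-type mouse neural stem cells, which were grown from newborn cortex in a growth-factor medium. Per the labels, 3 libraries were made, with 1 library per group: an immunoprecipitation for the nucleoporin Seh1, an immunoprecipitation with IgG (an antibody without a chromatin target, used as background control) and an input library of chromatin that was not precipitated. A peak list was analysed for the Seh1 and the IgG library. The names of both peak sets in the file headers pair each library with the input, and no separate values of the input library were used here. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication and libraries were prepared with a commercial kit.

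Each deposited list holds 1 line per peak with its chromosome, start and end. Per the file headers, the authors annotated the peaks with HOMER annotatePeaks.pl against mm10, the mouse assembly GRCm38. That step gave each peak an annotation class, the nearest transcription start site (TSS) of a RefSeq transcript with the signed distance in bp, and the gene of that TSS. Where the centre lay in a repeat, it also gave a repeat class, but only for peaks classed as intron or intergenic. Bowtie2 and HOMER are named without versions in the submitters' processing notes. Those notes list the human builds hg18 and hg38, whereas the file headers name mm10 and the genes are mouse genes; coordinates are therefore given in mm10. The peak caller, its threshold, any filter on multiply mapped reads or duplicates and the number of reads per library are not given in the sources used here. The deposited score was 0 for every peak in both lists, so the lists carry no peak height, fold enrichment or p-value, and the sequencing depth behind each peak is unknown. A peak list of this kind says where a caller found enrichment over input, and a longer list can come from deeper sequencing as well as from more binding. Peaks were listed per library and not on pooled libraries.

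With 1 library per group there were no replicates, and no test here compares conditions. Fisher's exact test (two-sided) compared the shares of the 2 peak lists, and each p-value describes those lists alone. Neighbouring peaks are not independent, so these p-values are too small. Shares carry 95% exact binomial (Clopper-Pearson) intervals, and ratios of shares carry 95% intervals on the log scale. Where a share was 0, the limit was set by 3 counts. All of these cover counting error only. The 65 share comparisons were adjusted together by the Benjamini-Hochberg method at a threshold of 0.05. The repeat names reported singly were picked because they were frequent in one of the lists.

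Peaks were called overlapping when they shared at least 1 bp. For the expectation under chance, peaks on the 21 placed chromosomes were set at random positions of their own chromosome 1000 times, between the first and last annotated gene. The smallest two-sided p that these placements can give is 0.001998. Gene positions came from the RefSeq gene table of GRCm38.p6, the same assembly as mm10, after 340 genes listed below 3 Mb on chromosomes other than Y were removed, because these coordinates belong to patches or unlocalised sequence. This left 49603 genes, of which 21779 were protein-coding. The table has no strand, so closeness to a TSS was taken from the authors' distance column, and random placements were compared by closeness to either end of a gene. The gene identifiers matched this table for 15972 of the 16033 Seh1 peaks and 5174 of the 5248 IgG peaks that carried one. For 246 Seh1 and 116 IgG peaks the authors' TSS lay off the gene of that identifier in the table (on another chromosome or over 1 kb beyond its ends), and an alternative left these peaks out.

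Before the data were examined, 11 gene lists with 401 genes were fixed: p53 targets and CDK inhibitors, cell cycle progression, neural stem cell, neuronal differentiation, astrocyte and oligodendrocyte, nuclear pore and GATOR2, chromatin repressors, Hox, synaptic and adhesion (fixed as a list of long genes), housekeeping and translation, and microglia with endothelium and fibroblast. All 401 matched the table, 1 of them through an older symbol. For each list the number of genes that the authors' annotation gave at least 1 peak was compared with 10000 random lists of protein-coding genes of the same size, matched on 10 strata of gene length. These random lists describe these libraries. P-values were two-sided and adjusted over the 11 lists of a library.

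The rule for the genes named in the text was also fixed before the data were examined. It takes Cdkn1a and Seh1l; up to 5 genes per list that were given a Seh1 peak not overlapping an IgG peak; the 10 strongest such Seh1 peaks; the 5 strongest IgG peaks; the 5 genes with the most Seh1 peaks; and the 5 strongest Seh1 peaks within 1 kb of a protein-coding TSS. The rule ranked peaks by fold or score. Because every score was 0, peak width was used in its place. For the same reason the planned stricter peak thresholds were replaced by keeping peaks wider than the median width of their list. The planned comparison of GC content was not made, since no genome sequence was used here. Other alternatives changed the overlap rule, the TSS distance (5 or 10 kb), the types of gene that counted, the way peaks were given to genes, the matching of random lists, and whether overlapping peaks or 1-Mb bins with at least 20 IgG peaks were left out.

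The functions were tested on simulated data. In 50 simulated pairs of lists with 100 planted overlaps, 101 ± 6.69 (SD) were recovered above chance. In 300 simulated gene lists of 40 genes drawn from 21779 genes with the Seh1 rates, an unadjusted p of 0.05 or less was reached by 3.67% of lists with no planted effect, 48.3% of lists with a 1.5-fold effect and 97.3% of lists with a 2-fold effect. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.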

Results

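Binding of the nucleoporin Seh1 to chromatin was profiled by ChIP-seq in mouse cortical neural stem cells at the proliferating stage. Seh1, encoded by Seh1l, is a subunit of the Nup107-160 complex of the nuclear pore and also of the GATOR2 complex. The Seh1 list held 16113 peaks that covered 4772 kb, with a median width of 266 bp and a range from 243 to 2002 bp. The IgG list held 5314 peaks that covered 1655 kb, with the same median width of 266 bp and a range from 236 to 2207 bp. In the Seh1 list 27.2% of peaks and in the IgG list 38% of peaks had the minimum width. Each group had 1 library, so no value below has a replicate error, and read depth is unknown.

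The series title names p21 as a gene repressed by Seh1, and the locus of its gene was examined first. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, held 1 Seh1 peak inside the gene. This peak of 466 bp lay on chromosome 17 from 29098401 to 29098866, in exon 2 of 3 of the RefSeq transcript, and its centre was 4864 bp downstream of the annotated TSS. It did not overlap an IgG peak, which sets it apart little, since only 60 of all 16113 Seh1 peaks (0.372%) did. It was wider than 95.7% of all Seh1 peaks. No Seh1 peak was given to Cdkn1a within 1 kb of its TSS. The IgG library also held 1 peak given to Cdkn1a, from 29102865 to 29103149, which was intergenic, 2.14 kb beyond the 3′ end of the gene and 4.37 kb from the centre of the Seh1 peak. The gene spans 9744 bp, from 29090979 to 29100722. Among the 2178 protein-coding genes in its stratum of length (7435 to 11728 bp), 23.5% were given a Seh1 peak, 5.51% were given an IgG peak and 2.30% had a Seh1 peak in an exon of one of their own transcripts.

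**Figure D1:**
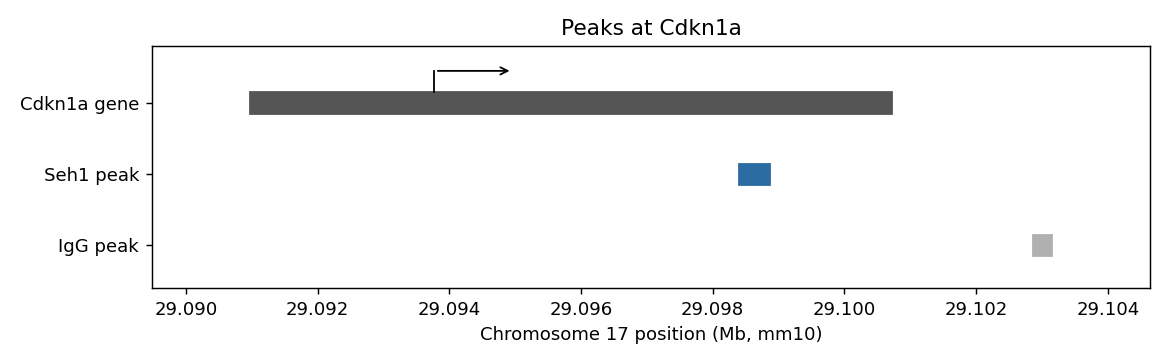
Map of the Cdkn1a locus on chromosome 17 (x axis, position in Mb, mm10), to scale, with the extent of the gene in the RefSeq table, the TSS used for the peak distances and its direction (arrow), and the called Seh1 and IgG peaks. The Seh1 peak lies inside the gene, 4864 bp from that TSS, and the IgG peak lies beyond the gene's 3′ end.

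Seh1l itself, at positions 67774876 to 67795487 of chromosome 18, also held 1 peak in each list. The Seh1 peak had the minimum width of 243 bp and lay in exon 4 of 8, from 67784905 to 67785147, at 10150 bp from the TSS. The IgG peak lay 1990 bp from the TSS, from 67776731 to 67777001. The peaks did not overlap.

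The IgG library served to find peaks that arise without a specific antibody. Of the 16113 Seh1 peaks, 60 overlapped an IgG peak, a share of 0.372% (95% exact binomial interval 0.284 to 0.479%). These lay mostly in a few regions: the chromosome 8 bins from 19 to 21 Mb, around Gm21119 and 6820431F20Rik, held 7 and 24 of the shared peaks, and the bin from 15 to 16 Mb on chromosome 5, around Gm21190 and genes of the Speer family, held 8. On the placed chromosomes 59 Seh1 peaks overlapped an IgG peak, against 20.1 (95% range 12 to 29) when Seh1 peaks were placed at random (permutation p = 0.001998, the smallest that 1000 placements can give). The excess rested on 13 bins of 1 Mb with at least 20 IgG peaks each, which held 46 of the 59; in the rest of these chromosomes 13 peaks overlapped, against 17 (9 to 25) by chance (permutation p = 0.38).

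Some of the widest peaks of both lists lay in such regions. The 5 genes with the most Seh1 peaks were Gm21119 with 50, 6820431F20Rik with 37, 1700030C10Rik with 25, 5730507C01Rik with 22 and Gm20871 with 20; the IgG list held 55, 34, 7, 3 and 2 peaks for these genes. The widest Seh1 peak without an IgG overlap spanned 1296 bp at the promoter of Gm21190. Others of the widest lay in exon 8 of 16 of Mecom, a zinc-finger transcription factor gene (1160 bp, chromosome 3 from 29979619 to 29980778), in the 3′ UTR class nearest to Tmem211 (1114 bp), in introns nearest to Mir6393 (925 bp) and Rab43 (894 bp), and in a B4A repeat nearest to Ajap1 (861 bp). The widest IgG peak spanned 2207 bp on chromosome 16 at 3246021 to 3248227, where the nearest annotated gene was Olfr161.

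Seh1 peaks were found in exons 4.92 times as often as IgG peaks. In the authors' exon class, which is kept apart from UTRs and non-coding exons, lay 866 Seh1 peaks (5.37%, interval 5.03 to 5.73%) and 58 IgG peaks (1.09%, 0.830 to 1.41%), a difference with an adjusted p of 1.7e-50 by Fisher's exact test. Introns held 36.8% of Seh1 and 33.5% of IgG peaks, and intergenic sequence held 54.3% and 62.5%, with adjusted p of 2.6e-05 and 2.4e-25 by Fisher's exact test. Transcription termination sites (1.03% and 0.979%), 3′ UTRs (0.919% and 0.960%) and 5′ UTRs (0.0993% and 0.0565%) did not pass the test. The exon peaks were spread over 805 transcripts, and 799 protein-coding genes, or 3.67% of them, held at least 1. Protein-coding genes contained 44.3% of Seh1 peak centres, above the 40.6% (95% range 39.9 to 41.4%) of random placements, and 37.3% of IgG peak centres, below the 40.1% (38.9 to 41.4%) of random placements (permutation p = 0.001998 for each, the smallest possible). The median Seh1 peak had 8 protein-coding genes within 500 kb, against a mean of 5.08 over random placements, and the median IgG peak had 5.

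Few peaks of either list lay at promoters. Within 1 kb of a protein-coding TSS were 246 Seh1 peaks, or 1.53% (1.34 to 1.73%), and 28 IgG peaks, or 0.527% (0.350 to 0.761%), which differed with an adjusted p of 3.0e-09 by Fisher's exact test. Within 5 kb the shares were closer, at 6.09% (5.72 to 6.47%) and 5.31% (4.72 to 5.94%). Set against random placement, however, 3.24% of Seh1 peaks lay within 1 kb of either end of a protein-coding gene, and 3.12% (2.86 to 3.40%) of randomly placed peaks did (permutation p = 0.44). For IgG the share was 2.25%, below the 3.01% (2.57 to 3.46%) of random placement (permutation p = 0.001998, the smallest possible). The centre of 11 Seh1 peaks and 1 IgG peak was annotated as a CpG island. The same annotation step labelled repeats only in introns and intergenic sequence. Whether it could label CpG islands at promoters or exons is not known, so these counts do not measure CpG islands there. The widest Seh1 peaks within 1 kb of a protein-coding TSS belonged, besides Gm21190 and Speer4c, to Ugt1a1, a bilirubin-conjugating enzyme (722 bp wide, 233 bp from the TSS), Lao1, an L-amino acid oxidase (718 bp, 82 bp), and Neb, the muscle protein nebulin (656 bp, 70 bp upstream).

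The lists differed most in the repeats they covered. Repeats were labelled only at peaks classed as intron or intergenic, and the shares below are of all peaks. LINE elements, nearly all of the L1 family, were at the centre of 31.8% of IgG peaks and 10.6% of Seh1 peaks, whereas long terminal repeat (LTR) retrotransposons were at the centre of 9.58% of IgG peaks and 17% of Seh1 peaks (adjusted p = 1.7e-261 and 2.5e-41 by Fisher's exact test). Among LTR families, ERVK, the family of intracisternal A particles, reached 9.91% in the Seh1 list and 5.29% in the IgG list, and ERV1 reached 1.48% and 0.452%. SINE elements were higher in the Seh1 list (6.90% and 4.86%), with the B4 family at 2.46% and 1.17% and the Alu (B1) family at 3.14% and 1.83%; the B2 family was lower (0.869% and 1.37%). Satellite repeats were at 0.180% of Seh1 and 1.77% of IgG peaks. For all of these families and classes the adjusted p was at most 0.00263 by Fisher's exact test.

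Some single repeat names, picked for being frequent in one of the lists, also differed. Young L1 elements of the L1Md_T and L1Md_A types were at 0.751% and 0.546% of Seh1 peaks but 5.95% and 3.41% of IgG peaks. L1Md_F2 went the same way, with 1.07% of Seh1 and 3.54% of IgG peaks. L1Md_F went the other way, with 0.701% of Seh1 and 0.320% of IgG peaks. RMER1A, RMER1B and RMER1C together were at 245 Seh1 peaks (1.52%) and 2 IgG peaks (0.0376%). The internal parts of RLTR10 and MTA elements were at 110 and 147 Seh1 peaks and at 1 and 5 IgG peaks. The major satellite GSAT_MM was at 70 IgG peaks (1.32%) and at 0 of 16113 Seh1 peaks, which allows a share of up to 0.0186%. Whether reads from repeats were mapped uniquely is not given in the sources used here, so the copy that a peak in a young repeat marks is uncertain.

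**Figure D2:**
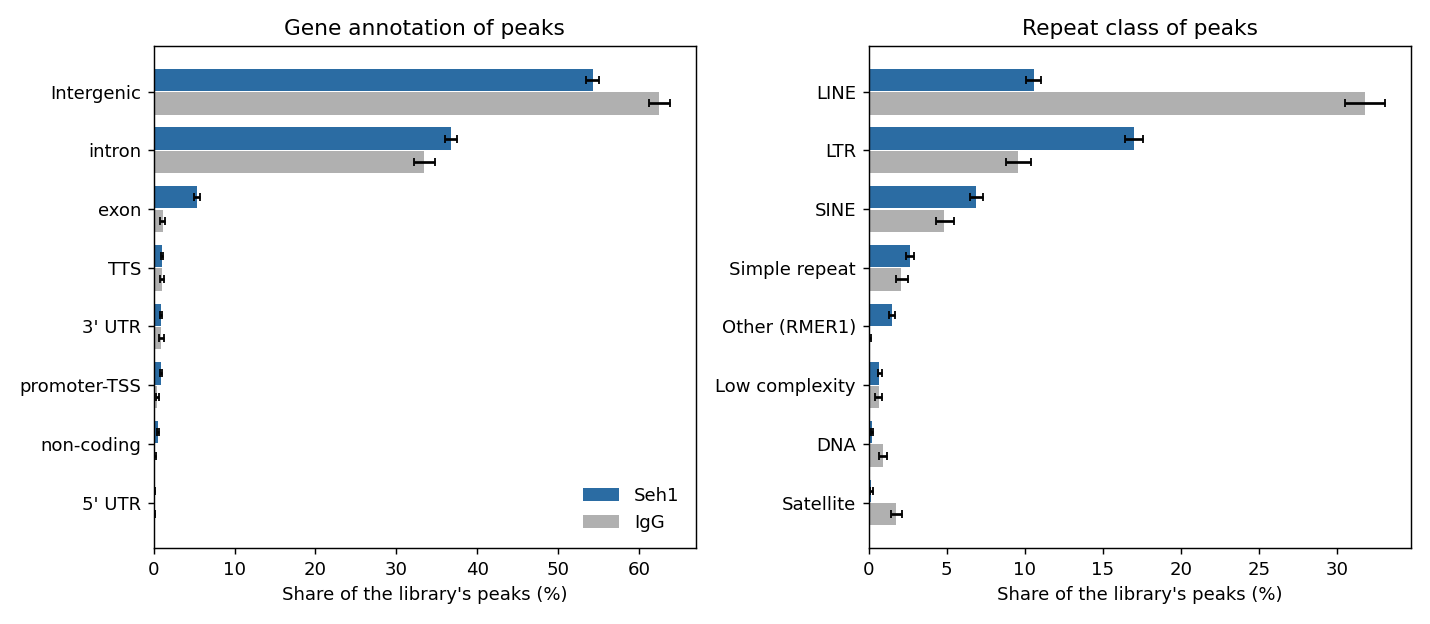
Share of each library's peaks (x axis, percent) in each gene annotation class (left) and repeat class (right), for 16113 Seh1 peaks (blue) and 5314 IgG peaks (grey). Bars start at 0 and error bars are 95% exact binomial intervals of counting error; exons hold 5.37% of Seh1 and 1.09% of IgG peaks, and LINE elements hold 10.6% and 31.8%.

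Of the 21779 protein-coding genes, 6938 (31.9%) were given at least 1 Seh1 peak and 2471 (11.3%) at least 1 IgG peak by the nearest TSS. Against this background none of the 11 gene lists departed from random lists of the same size and gene length in the Seh1 library after adjustment (lowest adjusted permutation p = 0.12), although 3 had an unadjusted p below 0.05. With 1 library, simulated lists of 40 genes with a 1.5-fold effect reached an unadjusted p of 0.05 or less in 48.3% of cases. The real lists were judged by an adjusted p, which is never smaller, and some held fewer genes. Effects of that size may therefore be missed more often than this rate implies.

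For each gene named from a list, the distance given is that of its widest Seh1 peak. Some of these genes also had peaks nearer to a TSS. The p53 target and CDK inhibitor list had 14 of 33 genes with a Seh1 peak, against a mean of 9.52 (95% range 5 to 15) in random lists (adjusted permutation p = 0.23). Besides Cdkn1a, the genes named by the rule were Cdkn2b, which encodes the inhibitor p15 (peak 127 kb upstream of its TSS), the pro-apoptotic genes Bbc3 (19.3 kb downstream, in an intron of Sae1) and Pmaip1 (75.5 kb upstream), and Rbl1, a member of the retinoblastoma family (17.8 kb downstream). Cell cycle progression genes had 12 of 40, against 11.4 (6 to 17), among them Cdk1, the mitotic kinase (12.2 kb upstream), Ccnd1, which encodes cyclin D1 (48.1 kb upstream), Mki67, which encodes the proliferation marker Ki-67 (2.69 kb upstream), Mycn (129 kb downstream) and the replication helicase gene Mcm2 (8.75 kb downstream). Their adjusted permutation p was 0.94.

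Neural stem cell genes had 22 of 44 with a Seh1 peak, against 16.0 (10 to 22; adjusted permutation p = 0.14). Examples were Hes1, an effector of Notch signalling (43.0 kb downstream, in an ERVK element), Tcf7l2 (29.5 kb), Sox1 (73.5 kb) and Prom1 (31.0 kb). Neuronal differentiation genes had 24 of 40, against 16.6 (11 to 22; unadjusted p = 0.0188, adjusted permutation p = 0.12), with peaks near Mapt, which encodes tau (9.38 kb upstream), Bcl11a (129 kb downstream), Eomes, a marker of intermediate progenitors (21.1 kb upstream), Rbfox3 (18.6 kb downstream, in an intron) and Fezf2 (195 kb upstream, in an intron of Cadps). Bcl11a also had a nearer peak, 12.1 kb downstream. Few genes of these lists had a peak within 10 kb of the TSS. They were 2 of 44 neural stem cell, 3 of 40 neuronal differentiation and 3 of 33 p53 target and CDK inhibitor genes. Ratios of observed to expected genes were then 0.469, 0.743 and 0.927, in place of 1.38, 1.45 and 1.47. None passed, and such small counts do not show depletion. Random lists matched on territory (the gene with its share of the gaps to neighbouring genes) gave means of 21.3 (15 to 27), 18.4 (13 to 24) and 11.3 (6 to 16). No list passed with this matching (lowest adjusted permutation p = 0.44). Housekeeping and translation genes had 3 of 40, including Rpl32, against 9.10 (4 to 15; unadjusted p = 0.0226, adjusted permutation p = 0.12). One of the 3 was Ppia, whose peaks lay on chromosome 9 although the gene lies on chromosome 11. Without peaks whose annotated TSS lay off its gene, the count was 2 of 40 against 8.94 (4 to 14; adjusted permutation p = 0.066). Hox genes had 4 of 39, against 9.18 (4 to 15; adjusted permutation p = 0.14). The Hox genes were Hoxd8, with a peak 520 bp upstream of its TSS, and Hoxd1, Hoxc13 and Hoxb13, with peaks 7.79 to 27.1 kb away.

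The remaining lists did not pass either. Chromatin repressor genes had 13 of 40 (15.3 expected), including the Polycomb genes Cbx2 (5.44 kb upstream), Eed (22.9 kb upstream) and Suz12 (34.9 kb downstream) as well as Mta3 (23.2 kb downstream) and Brd7 (73.6 kb upstream). Nuclear pore and GATOR2 genes had 10 of 33 (12.5 expected). Among them were Nup133 (13.8 kb downstream), Nup210 (94.2 kb downstream) and Nup85 (8.57 kb upstream). Others were Sec13 (46.9 kb upstream, in an intron of Atp2b2) and Nup153 (89.4 kb upstream, in an intron of Kif13a). Astrocyte and oligodendrocyte genes had 11 of 28 (9 expected), including Nkx6-2 (10.8 kb upstream), Enpp6 (149 kb downstream) and Bcas1 (18.7 kb downstream). Slc1a2, the glial glutamate transporter (23.6 kb downstream), and Gpr17 (10.3 kb upstream) were also among them. Enpp6 and Bcas1 also had nearer peaks, 5.67 and 3.33 kb downstream. The Gpr17 peak lay in an exon of the neighbouring Myo7b. The list for other cell types that such a culture could hold, with microglial, endothelial and fibroblast genes, had 10 of 24 (8.30 expected). It included Cx3cr1 (595 bp wide, in its intron), Col3a1 (74.5 kb upstream), Cdh5 (109 kb upstream), Cldn5 (25.6 kb upstream) and Kdr (136 kb downstream). The adjusted permutation p was 0.64 for each of these 4 lists. Synaptic and adhesion genes had 31 of 40 (24.6 expected, unadjusted permutation p = 0.0456, adjusted permutation p = 0.14). They included Dab1 (104 kb downstream), Csmd1 (194 kb downstream), Grm7 (425 kb upstream) and Grm8 (0.89 kb downstream). Grm7 also had a nearer peak, 1.44 kb downstream of its TSS.

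The synaptic and adhesion list was fixed as a list of long genes. In the IgG library it was the only one of the 11 to pass, with 28 of 40 genes against 12.7 (7 to 19, adjusted permutation p = 0.0044). With random lists matched on 100 strata of length in place of 10 it did not (24.7 expected, adjusted permutation p = 0.81). Of its 40 genes, 26 held peaks of both libraries. The other lists in the IgG library had 0 of 39 Hox genes, 1 of 40 cell cycle genes, 4 of 33 p53 target and CDK inhibitor genes, 10 of 44 neural stem cell genes, 10 of 40 neuronal differentiation genes, 6 of 40 chromatin repressor genes, 3 of 33 nuclear pore and GATOR2 genes, 3 of 40 housekeeping and translation genes, 2 of 28 astrocyte and oligodendrocyte genes and 1 of 24 microglial, endothelial and fibroblast genes. Their adjusted permutation p was 0.55 or more.

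**Figure D3:**
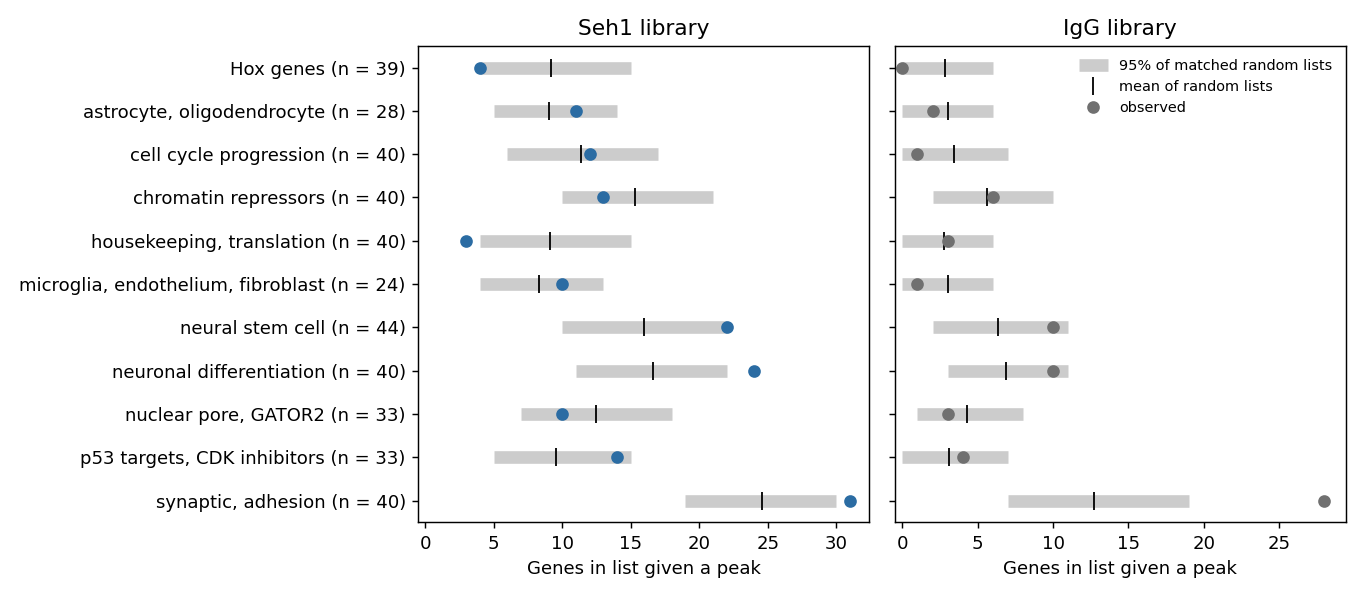
Number of genes in each of the 11 gene lists (y axis, with list size n) that were given at least 1 peak (x axis, genes), for the Seh1 (left) and IgG (right) library. Points are observed numbers, ticks are means and grey bars 95% ranges of 10000 random lists matched on gene length. The point for synaptic and adhesion genes, a list of long genes, in the IgG library, 28 of 40, is the only one past the threshold after adjustment. It is not with 100 strata of gene length (adjusted permutation p = 0.81).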

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

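The alternatives that kept wider peaks, left out bins dense in IgG peaks, left out overlapping peaks from the class shares, left out peaks with a TSS off its gene, or changed the matching of random lists were chosen after seeing the data. The number of Seh1 peaks overlapping an IgG peak, 60, was 53 with an overlap of at least 50% of the shorter peak and 42 among wider peaks; it was 122 with centres within 1 kb and 14 without the dense bins. The share of Seh1 peaks near a TSS, 1.53%, was 6.09% within 5 kb, 1.92% with TSSs of all genes and 1.79% among wider peaks, and the IgG share, 0.527%, was 5.31% within 5 kb, where the 2 lists lay closer together than within 1 kb. The shares inside protein-coding genes were 43.5% (Seh1) and 35.7% (IgG) among wider peaks. The exon, L1 and ERVK shares of both lists stayed inside the intervals of the reported values under each of the 3 alternatives tried. No gene list passed in the Seh1 library under any of the 8 alternatives (0 of 11; lowest adjusted permutation p 0.066). Ratios of observed to expected genes changed sides of 1 for lists that did not pass. With peaks given by gene body and 5 kb either side (the table has no strand, so the planned upstream side could not be chosen) they were 0.833 for cell cycle, 1.18 for chromatin repressors, 0.938 for microglia with endothelium and fibroblast, and 0.999 for p53 targets. Within 10 kb of the TSS they were 0.996 for cell cycle, 0.832 for microglia with endothelium and fibroblast, 0.469 for neural stem cell, 0.743 for neuronal differentiation and 0.927 for p53 targets. Among wider peaks they were 1.02 for chromatin repressors and 0.942 for microglia with endothelium and fibroblast. The cause was not tested. The thresholds on fold or score and the GC content were not run, because the scores are all 0 and no genome sequence was used here. The unknown depth limits every count of peaks.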

Other observations

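The tests of the exon pattern and the leaving out of bins dense in IgG peaks were chosen after the results were seen. The matching on territory and on 100 strata of gene length was added after the data were seen, but what each would show was written down before its result. Of the genes in this paragraph, those outside the rule for named genes were named after their values were seen. Of the 401 genes on the lists, 154 were given a Seh1 peak, at a median distance of 59.7 kb over their 315 peaks (37792 bp over all Seh1 peaks). In 3 of these genes a peak lay within 1 kb of the TSS: Hoxd8, Grm8 and Cspg4, which encodes the oligodendrocyte precursor marker NG2 (729 bp upstream). Among all Seh1 peaks, 1.53% lay that close to a protein-coding TSS, which is a share of peaks and not of genes. In 10 of the 401 genes a Seh1 peak lay in an exon of the gene's own transcript: Cdkn1a, Mcm5, Seh1l, Nup210, Hdac4, Dnmt3a, Setdb1, Nrxn3, Cntnap2 and Acta2. Of all protein-coding genes, 3.67% held an exon peak, so these lists show no excess. Hdac4, a class II histone deacetylase, had peaks in exons 6 and 8 of 27, and Dnmt3a, a de novo DNA methyltransferase, had a peak in exon 14 of 18.

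Seh1 peaks were also dense in single regions with few IgG peaks. The bins named next were picked, after their values were seen, as those without an IgG peak among the bins with the most Seh1 peaks. Tshz3 was also named after its values were seen. How often a bin holds no IgG peak by chance was not computed, so these bins are not shown to be particular to Seh1. The bin from 88 to 89 Mb on chromosome 1, around Mroh2a and Ugt1a1, held 25 Seh1 and 0 IgG peaks, the bin from 179 to 180 Mb on chromosome 2, around Cdh4, held 25 and 0, and the bin from 48 to 49 Mb on chromosome 17, around Lrfn2, held 24 and 0. Tshz3, a zinc-finger homeobox gene, had 16 Seh1 and 0 IgG peaks. Chromosomes 5, 7, 9, 11, 17, 19 and Y held a larger share of Seh1 than of IgG peaks and chromosomes 3, 4, 13 and 14 a smaller one, each with an adjusted p below 0.05 by Fisher's exact test. Each of the latter 4 holds at least 1 bin dense in IgG peaks. So do chromosomes 5 and 9, with a larger Seh1 share, and chromosomes 8, 16 and X, which did not pass the test.

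Seh1 peaks lay in exons 4.92 times as often as IgG peaks (95% interval 3.78 to 6.41). A larger share of peaks inside genes does not by itself account for this, since among peaks in exons or introns alone the exon share was still 4.04 times as high (3.11 to 5.24). Whether gene-rich regions contribute is left open, because peaks were not matched on gene density. The median Seh1 peak had 8 protein-coding genes within 500 kb and the median IgG peak had 5. Only 6.21% of the transcripts with an exon peak held 2 or more. This argues against spliced RNA, cDNA or plasmid carried into the library in amounts that mark whole transcripts. The share expected from scattered peaks was not computed. Carry-over too weak to give several peaks per transcript is not excluded, since depth and peak heights are unknown. Nor does the 6.21% bear on a single locus such as Cdkn1a. Fragments from the 3′ end were not tested apart and are not excluded. Of the exon peaks, 19.4% lay in the last and 6.70% in the first exon, where the median number of exons was 14. However, 3′ UTRs, which are kept apart from the exon class, held 0.919% of Seh1 and 0.960% of IgG peaks and did not pass the test. A difference in base composition between the libraries remains open and is consistent with the simple repeats under the peaks, whose repeat units held 58.9% ± 12.3 G and C (SD over 423 Seh1 peaks) against 34.9% ± 17 (112 IgG peaks), a difference of 23.9 points (20.6 to 27.2; permutation p = 1e-05, the smallest that 100000 permutations can give). None of these simple repeats lay at a peak of the exon class, since repeats were labelled only in introns and intergenic sequence. Whether recovery that rises steadily with G and C could be the whole cause is left open. The rule for this test first used the promoter class alone, which argued against it, and was widened to 2 promoter measures after that result. The ratio of shares was 1.95 (1.27 to 3.0) in the promoter class, below that in exons. It was 2.90 (1.96 to 4.28) within 1 kb of a protein-coding TSS, where the interval overlaps that in exons. The 1 kb measure also counts peaks of the exon class, such as that at Ugt1a1, so it does not measure promoters apart from exons. No G and C content was measured at promoters or exons. Binding of Seh1 in exons was not tested.

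The 59 overlaps of Seh1 and IgG peaks on placed chromosomes exceeded chance, and clustering of both lists in the same few regions is a candidate explanation. Moving each Seh1 peak at random by up to 500 kb gave 31.3 overlaps on average with an upper limit of the 95% range of 42, above random placement on the chromosome (20.1) but below the real number, so clustering at this scale accounts for part of the excess at most. Outside the 13 dense bins, which held 1.88% of Seh1 and 11.3% of IgG peaks, 13 overlaps stood against 17 by chance. What is left open is whether the remainder in the dense bins comes from reads shared between near-identical copies at a finer scale, which peak positions alone cannot show. No biological explanation was tested.

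The IgG excess at synaptic and adhesion genes, a list of long genes, may reflect their length. Matching on the territory around each gene left the list past the threshold (28 genes against 15.7, adjusted permutation p = 0.0044), so territory in 10 strata is argued against, whereas matching on 100 strata of gene length gave 24.7 expected genes and an adjusted permutation p of 0.81. In the Seh1 library the same finer matching gave 30.0 expected genes against 31 observed.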
